A study of Homo sapiens with 12 samples.

How the data were processed

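Gene expression was measured by RNA sequencing in 12 libraries, 3 from each of 4 groups: the unedited RUES2 line (WT) and lines with mutations of Hermansky-Pudlak syndrome types 1, 2 and 8. Per the labels' protocols, the cells were differentiated to day 40 lung organoids, EPCAM-positive cells were sorted, RNA was extracted with TRIzol and a Direct-zol kit, and libraries were made from poly-A RNA with a TruSeq kit and sequenced on a HiSeq2500. The authors deposited 2 tables of read counts per gene, with whole numbers and a different total in each library, 1 by gene symbol and 1 by Ensembl gene identifier. All 21962 genes had identical counts in both tables, so each symbol was paired with the identifier on the same line. Per the submitters' processing notes, bcl2fastq 2.17, STAR 2.5.2b, featureCounts 1.5.0-p3, DESeq2 and the genome build GRCh37 were used, with no roles or order stated. The strand setting, the gene annotation and the version of DESeq2 used by the authors are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may have been assigned to either gene, and such genes are uncertain.

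Each library was placed in its group by its label, and the 12 count columns were matched to the labels by name. The labels do not say that replicates of a group came from separate cultures, so p values measure only the spread between these libraries, which may be technical. The counts of replicate pairs differed beyond sampling noise, with a chi-square per gene of 17.75 to 137.4 over genes with at least 100 counts, so no library was counted as a repeat of another. Total counts ranged from 10404101 to 25196127. Of the 21962 genes, 21954 had an Ensembl identifier, 21605 matched a current symbol in a reference of another build, and 2607 had no counts in any library. Symbols are those of the deposited tables. The reference was used for chromosome, gene type, transcript length and GC content, and no coordinates are given. Of the genes tested, 15103 (99.1%) had a length and a GC content.

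Genes were tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited, after filterByExpr, which left 15233 genes, with TMM scaling and 1 quasi-likelihood fit over all 12 libraries in which each group had its own mean. The 6 comparisons between groups were contrasts of that fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 change was its size divided by the square root of the F statistic. CPM were computed from the TMM-scaled library sizes, and principal components from log2 CPM with a prior count of 2. Genes called in common between comparisons with the same WT libraries were set beside the overlap of independent lists and beside simulations of unchanged groups that share their controls. Before the data were examined, 32 gene lists for lung cell types, other cell types, pathways and RNA quality were fixed, with 607 of their 640 genes in the tables and 31 lists large enough to test. The list not tested was that for RNA quality, since 0 of its 13 mitochondrially encoded genes were found in the tables. RNA quality was therefore not checked by a list. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera asks whether the genes of a list rank above or below all other genes, and fry asks whether they move, on balance, in 1 direction. No camera call in any of the 6 comparisons was kept with an estimated correlation.

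The groups, the fits, the comparisons, the gene lists, the rule for the genes named and the alternatives were also fixed before the data were examined, except those described as chosen later. Named genes were HPS1, AP3B1 and BLOC1S3; for each comparison with WT, the 8 higher and 8 lower genes with the largest log2 change among those past the threshold whose CPM did not overlap between the groups (10% of genes would meet this last condition by chance) and whose higher group averaged at least 5 CPM; up to 4 members with the smallest p of each list called in a comparison with WT; up to 10 genes in each direction that set HPS1 and HPS2 apart from both WT and HPS8; 4 and 4 genes for each comparison without WT, by the same conditions; and IL11, SFTPC, SFTPB, EPCAM, COL1A1 and VIM in every comparison. The gene NKX2-1 was also fixed for every comparison, but it was not found in the deposited data under that symbol. Its level was therefore not read in any group. Clone names, RNA genes and pseudogenes were left out. Not all members of a fixed list were analysed here.

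The steps were first tested on simulated data for HPS1 against WT, with counts drawn from the means, dispersions and library sizes of the real libraries over 15099 genes. At a false discovery rate of 0.05, edgeR found 33 of 100 genes changed 2-fold and 78 of 98 changed 4-fold, with 5.13% of its calls false. DESeq2 found 43 and 81, with 13.9% of its calls false. A simulated list changed 2-fold was called by camera (adjusted p = 2.42e-33) together with 2 of 30 other lists. Camera with an estimated correlation (adjusted p = 2.5e-05) and fry (adjusted p = 7.76e-07) also called it, each with 1 of 30 other lists. Genes were simulated independently of each other, so these calls do not cover real correlation between genes.

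Alternatives were the size factors of DESeq2 1.42.0 in edgeR, the Wald test of DESeq2, no filter on low counts, a filter of at least 5 CPM in 3 libraries, a fit of the 2 groups compared alone, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen was an offset that removed from each library a spline trend (5 degrees of freedom each) of log2 CPM on transcript length and on GC content, alone or with the replicate block, and camera with the size factors of DESeq2. Replicate numbers in the labels run from 1 to 3 in every group, and the labels do not say that a number marks a shared differentiation. Deviations from the group means of same-numbered libraries correlated across genes at 0.1024, 0.1456 and 0.1897 for HPS1 and WT, all over 0.1, so for that comparison the numbers were taken to pair the libraries, as a property of the data. Pairs in the 5 other comparisons did not all exceed 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.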

Results

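Messenger RNA was measured in lung epithelial cells grown from RUES2, an established human embryonic stem cell line. The cells were taken through definitive endoderm and anterior foregut endoderm to day 40 organoids in Matrigel, and EPCAM-positive cells were sorted before RNA extraction. The unedited line (WT) was set against lines edited with CRISPR to carry mutations of Hermansky-Pudlak syndrome type 1 (HPS1), type 2 (HPS2) or type 8 (HPS8). The syndrome is an inherited disorder of lysosome-related organelles. Lung fibrosis is known for types 1 and 2 and not for type 8. Each of the 4 groups had 3 libraries. Total counts ran from 17840192 to 20118871 in WT, from 10404101 to 21313076 in HPS1, from 14633235 to 18572321 in HPS2 and from 16553137 to 25196127 in HPS8. Of the 21962 genes in the tables, 15233 had enough counts to be tested. Changes are log2 ratios of the first group to the second ± the standard error (SE). Levels are mean CPM (counts scaled to the same library total) ± the standard deviation (SD) over n = 3 libraries per group. Adjusted p values are from the quasi-likelihood test of edgeR unless another tool is named.

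The genes of the 3 syndrome types were examined first, since each edited line is named after one of them. AP3B1 on chromosome 5 (ENSG00000132842) is the gene of type 2 and encodes a subunit of the AP-3 adaptor complex. It fell in the HPS2 line by 1.31 ± 0.248 on the log2 scale against WT (adjusted p = 0.0306). Its libraries had 44.23, 20.22 and 33.95 CPM, against 95.29, 78.58 and 70.93 CPM in WT. The HPS1 gene on chromosome 10 (ENSG00000107521) was at 41.7 ± 8 CPM in the HPS1 line and 62.6 ± 12 CPM in WT. The difference did not pass the test (log2 change -0.59 ± 0.188, adjusted p = 0.0948). BLOC1S3 on chromosome 19 (ENSG00000189114), the gene of type 8, was at 8.17 ± 2.33 CPM in the HPS8 line and 8.79 ± 1.15 CPM in WT. The difference was smaller than the spread between replicates (log2 change -0.11 ± 0.265, adjusted p = 0.779). An edited transcript need not fall in amount, so the last 2 values do not go against the labels. The HPS1 gene rose in the HPS8 line (log2 change 0.90 ± 0.188, adjusted p = 0.00257). AP3B1 did not pass the test in HPS1 (-0.03 ± 0.243, adjusted p = 0.959) or HPS8 (-0.47 ± 0.244, adjusted p = 0.144). The call for AP3B1 in HPS2 was lost when only the 2 groups entered the fit (adjusted p = 0.051) and without WT replicate 1 (0.126) or 3 (0.102) or HPS2 replicate 1 (0.052), 2 (0.0853) or 3 (0.0733), within a range of 0.000158 to 0.126 over all alternatives. The HPS1 gene passed in the HPS1 line once a trend on transcript length and GC content was taken out (-0.99 ± 0.14, adjusted p = 0.0136; 0.0136 to 0.333 over all alternatives).

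**Figure D1:**
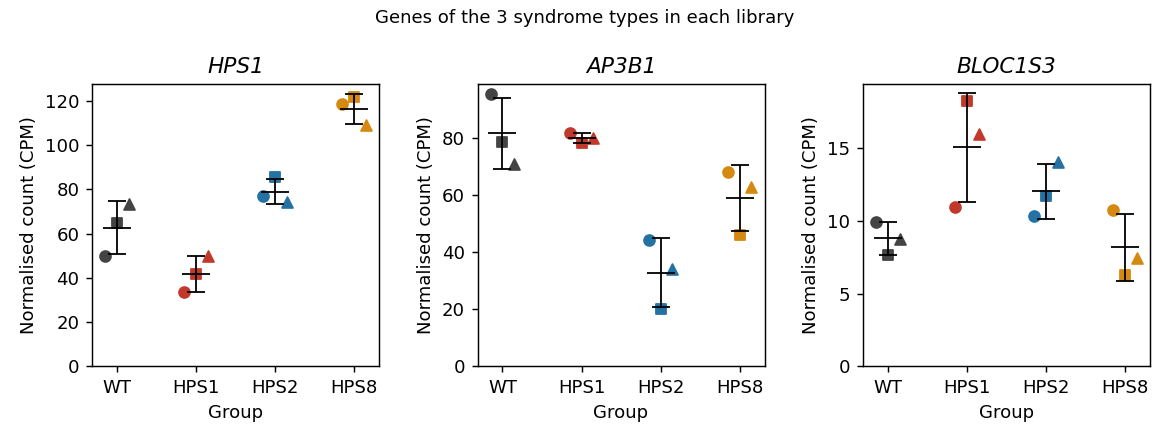
CPM (y axes, from 0) of HPS1, AP3B1 and BLOC1S3 in the 3 libraries of each group (x axes), with circles, squares and triangles for replicates 1, 2 and 3, a bar at the mean and error bars of 1 SD. The 3 HPS2 libraries lie at 20.22 to 44.23 CPM of AP3B1 and the 3 WT libraries at 70.93 to 95.29 CPM.

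The HPS8 libraries stood apart from all others. The first principal component held 43.2% of the variance of log2 CPM. The HPS8 libraries lay on it at 65.78 to 91.97, the WT libraries at -51.59 to -36.75 and the HPS1 libraries at -32.5 to -15.38. HPS2 replicate 3 lay at 18.52 on this axis, nearer to HPS8 than HPS2 replicates 1 (-30.75) and 2 (-21.29). The second component (16.7%) spread the HPS1 libraries from -67.42 to -7.063. Against WT, 5710 genes changed in HPS8 (37.5% of those tested), 360 in HPS1 and 153 in HPS2.

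**Figure D2:**
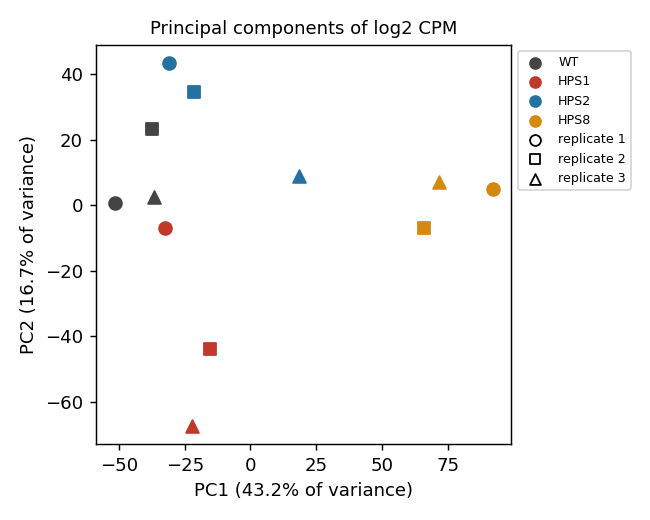
Position of the 12 libraries on the first (x axis, 43.2% of the variance) and second (y axis, 16.7%) principal components of log2 CPM, coloured by group, with the marker shape giving the replicate number. The HPS8 libraries lie at 65.78 or more on the first axis and HPS2 replicate 3 at 18.52.

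The HPS1 line was compared with WT to ask which genes differ in a line with a mutation of type 1, a subtype with lung fibrosis. In this and all other comparisons, with 1 line per genotype, a mutation cannot be told apart from other differences between lines or differentiations. SOX17, an endoderm transcription factor, had the largest increase among the genes named (4.82 ± 1.03, adjusted p = 0.0323), from a low level of 0.238 CPM to 7.12 CPM. The growth factor IGF2 rose from 18.1 ± 3.77 to 99.8 ± 38.7 CPM (log2 change 2.46 ± 0.371, adjusted p = 0.0175). The axon guidance ligand SLIT1 rose from 13.0 ± 1.11 to 72.7 ± 17.7 CPM (2.48 ± 0.386, adjusted p = 0.0175). CEACAM5, HAVCR1, TSPAN18, ADAMTSL2 and the hedgehog ligand IHH rose by 2.16 to 2.85 on the log2 scale. SOX17, HAVCR1, TSPAN18 and IHH also rose in HPS8 against WT, by 5.48, 2.80, 2.97 and 2.60 (adjusted p of 0.00145, 0.00148, 0.000605 and 0.00235), a comparison of these 4 genes chosen after their values were seen. The largest decreases were in C9orf64 (-4.25 ± 0.617, adjusted p = 0.0175), PCP4 (-3.95 ± 0.802, adjusted p = 0.0285; -5.94 without HPS1 replicate 3) and the interferon-induced OAS3 (-3.38 ± 0.768, adjusted p = 0.0378). Next came KCNJ15, the secreted trefoil peptide TFF3, GDF9, GUCY1B3 and the prostaglandin receptor PTGER3 (-2.74 to -2.16). OAS3 was at 0.4967 to 1.05 CPM in HPS1. It also had 0.5503 CPM in HPS2 replicate 2, against 13.32 and 13.38 CPM in HPS2 replicates 1 and 3. Single libraries moved KCNJ15 (-3.49 without HPS1 replicate 3), GUCY1B3 (-1.72 without WT replicate 1) and SOX17 (5.94 without WT replicate 3) by over 1.5-fold. In all, 205 genes were higher and 155 lower, of which 132 and 101 differed at least 2-fold. By comparison, 3495 genes had an unadjusted p under 0.05.

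Of the fixed gene lists, 5 were called by camera in HPS1 against WT. Of 23 extracellular matrix and collagen-modifying genes, 2 rose and the others did not pass (9 adjusted over the list alone). Fibronectin, FN1, rose from 1040 ± 88.8 to 2035 ± 192 CPM (log2 change 0.97 ± 0.178, adjusted p = 0.0226). The basement membrane collagen COL4A2 rose by 1.02 ± 0.233 (adjusted p = 0.0378). P4HA2 (0.71, adjusted p = 0.0526) and COL6A1 (0.85, adjusted p = 0.0649) did not pass, but did with the replicate block (0.0426 and 0.0439, within 0.00398 to 0.301 and 0.00988 to 0.325 over their alternatives). This list tended upward (camera adjusted p = 3.81e-07; adjusted p = 0.695 with an estimated correlation). Mesenchymal cell markers had a median of 0.33 without a call (adjusted p = 0.0846). Non-lung endoderm markers had a median of 1.08, also without a call (adjusted p = 0.0752), with library scores of 0.344 to 0.938 in HPS1 and at most 0.229 in WT. Of 25 lysosomal genes, 3 rose (5 adjusted over the list alone). They were the lysosomal gene regulator TFEB (0.85 ± 0.178, adjusted p = 0.0304), the saposin precursor PSAP (0.91 ± 0.18, adjusted p = 0.0258) and the peptidase TPP1 (1.34 ± 0.275, adjusted p = 0.03). The list went up with an adjusted p of 1.41e-05 (adjusted p = 0.695 with an estimated correlation). Of 24 oxidative phosphorylation genes, UQCRQ of complex III fell (-0.87 ± 0.212, adjusted p = 0.0482), and 1 gene fell adjusted over the list alone. The list went down (adjusted p = 0.003; adjusted p = 0.695 with an estimated correlation). Of 22 hypoxia and glycolysis genes, the glucose transporter SLC2A1 rose (1.32 ± 0.264, adjusted p = 0.0258), 1 also adjusted over the list alone. The list went up (adjusted p = 0.0274, and adjusted p = 0.695 with an estimated correlation). Its library scores were 0.324, 0.502 and 0.017 in HPS1 and -0.255, 0.403 and -0.148 in WT, so the ranges overlapped. None of 18 epithelial identity genes passed over all genes and 1 did adjusted over the list alone. Values were for PRSS8 0.82 ± 0.211 (adjusted p = 0.0557; 0.0482 with the block, within 0.00591 to 0.301 over its alternatives), for CDH1 0.51 (0.123), for CLDN7 0.52 (0.143) and for ST14 0.48 (0.183). The list was called upward (adjusted p = 0.0281; adjusted p = 0.695 with an estimated correlation). Over all alternatives the adjusted p of the 5 lists ran from 2.27e-09 to 0.695. In 7 of the 10 splits of these 6 libraries camera called at least 5 lists.

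The number of genes called in HPS1 against WT rested on single libraries. It was 0 without WT replicate 3 (2842 at an unadjusted p under 0.05), 0 without HPS1 replicate 2 (1895), 14 without WT replicate 2, 152 without WT replicate 1, 281 without HPS1 replicate 3 and 2311 without HPS1 replicate 1. The epithelial list was lost without WT replicate 3 (0.157), HPS1 replicate 2 (0.0585) or HPS1 replicate 3 (0.0778). The hypoxia list was lost without WT replicate 1 (0.253), WT replicate 3 (0.137), HPS1 replicate 1 (0.24) or HPS1 replicate 2 (0.154), and the oxidative phosphorylation list without WT replicate 2 (0.0545). The matrix and lysosomal lists passed without any one library. The count was 347 higher and 255 lower with the replicate number as a block. It was 77 and 40 with the length and GC trend taken out, of which 55 and 27 were among the 205 and 155. COL4A2 then no longer passed, with its change nearly halved (0.54 ± 0.22, adjusted p = 0.222). SOX17 (4.64 ± 1.06, adjusted p = 0.0614), IHH (1.95 ± 0.537 from 2.21 ± 0.53), ADAMTSL2 (1.74 ± 0.473 from 2.16 ± 0.486), PCP4 (-3.12 ± 0.917), KCNJ15 (-2.48 ± 0.546 from -2.74 ± 0.544), TFF3 (-2.49 ± 0.624 from -2.61 ± 0.609), GDF9 (-2.20 ± 0.551 from -2.46 ± 0.537) and GUCY1B3 (-2.05 ± 0.445 from -2.37 ± 0.472) were also lost. So were PSAP (0.67 ± 0.174), TPP1 (1.15 ± 0.264), TFEB (0.56 ± 0.128), SLC2A1 (1.06 ± 0.261) and UQCRQ (-0.61 ± 0.144). FN1 (1.12, adjusted p = 0.0136) and IGF2 (1.90, adjusted p = 0.0136) still passed, in ranges of 8.54e-06 to 0.17 and 5.38e-08 to 0.139 over their alternatives, while the epithelial (0.225), oxidative phosphorylation (0.105) and hypoxia (0.0778) lists did not.

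The HPS2 line was compared with WT to ask the same of type 2, the other subtype with lung fibrosis. The endothelial nitric oxide synthase NOS3 rose from 30.4 ± 7.34 to 142.6 ± 13.0 CPM (log2 change 2.23 ± 0.283, adjusted p = 0.0154). Increases were also found for RBFOX1 (2.29 ± 0.354, adjusted p = 0.0241), the inducible heat shock protein HSPA6 (2.15 ± 0.354, adjusted p = 0.0248) and the thyroid hormone-inactivating enzyme DIO3 (1.90 ± 0.318, adjusted p = 0.0258). Calretinin, CALB2 (2.01 ± 0.442, adjusted p = 0.0479), SYT4 and SLC19A3 rose as well. SOX17 rose by 4.72 ± 1.02 (adjusted p = 0.0459). It had 16.2 CPM in HPS2 replicate 3 and 2.07 and 1.79 CPM in the other libraries of the line. SYT4 (26.8 CPM against 7.87 and 8.67) and SLC19A3 (70.2 CPM against 16.7 and 23.2) were also highest in HPS2 replicate 3. Without that library SOX17, SYT4 and SLC19A3 were at 2.92, 1.34 and 1.19 and did not pass (adjusted p of 0.107, 0.0841 and 0.11). The largest decreases were in the adhesion molecule MCAM (-2.95 ± 0.584, adjusted p = 0.0361) and pleiotrophin, PTN, which went from 18.6 ± 5.72 to 3.10 ± 0.536 CPM (-2.58 ± 0.338, adjusted p = 0.0154). FILIP1, KIF5C, MAMLD1, PKNOX2, the lysolipid transporter MFSD2A (-2.10 ± 0.34, from 99.6 ± 30.5 to 23.3 ± 5.41 CPM) and PIK3R3 (-2.08 ± 0.328) followed. By a comparison made after the values were seen, NOS3 and PTN also lay outside the WT range in HPS1 and HPS8. NOS3 was at 85.78 to 154.5 CPM in HPS1 and 53.56 to 106.5 in HPS8, against at most 38.9 in WT. PTN was at 4.037 to 8.174 and 2.726 to 3.768 CPM, against at least 12.04 in WT. Not all named genes did so: RBFOX1 in HPS8 (1.992 to 5.579 CPM) and MFSD2A in HPS1 (49.8 to 130.3 CPM) overlapped WT. Without WT replicate 1 MCAM and KIF5C were at -2.30 and -1.60 and did not pass (0.145 and 0.107), and SOX17 was at 5.85 without WT replicate 3 (0.143). In all, 64 genes were higher and 89 lower, 57 and 75 of them at least 2-fold, with 2672 genes at an unadjusted p under 0.05.

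Of 17 lung and foregut endoderm transcription factors, 4 fell in HPS2 against WT, also 4 adjusted over the list alone. They were IRX2 (-1.38 ± 0.22, adjusted p = 0.0241), ETV5 (-1.14 ± 0.215, adjusted p = 0.0306), FOXP2 (-1.33 ± 0.272, adjusted p = 0.0378) and IRX1 (-1.45 ± 0.312, adjusted p = 0.0454). The list was called downward by camera (adjusted p = 0.026, and adjusted p = 0.58 with an estimated correlation). These 4 genes were also lower in HPS8 than in WT, a comparison made after their values were seen. Their highest HPS8 and lowest WT libraries had 63.58 and 114 CPM (IRX2), 173.8 and 266.3 (ETV5), 23.52 and 70.92 (FOXP2) and 41.08 and 46.83 (IRX1). FOXP2 was also lower in HPS1 (33.27 to 47.08 CPM), whereas IRX2, ETV5 and IRX1 overlapped between HPS1 and WT. In HPS8 against WT camera did not call the list (adjusted p = 0.392). Of 20 non-lung endoderm markers, none passed over all genes by edgeR, and 7 rose and 1 fell adjusted over the list alone. Their median was 1.14 without a call (adjusted p = 0.0919), and HPS2 replicate 3 scored 2.137, against -0.541 and 0.12 in HPS2 replicates 1 and 2. Of 18 mesenchymal cell markers, THY1 fell (-2.55 ± 0.444, adjusted p = 0.0286), and 1 rose and 1 fell adjusted over the list alone. ACTA2 was at 1.02 without passing (adjusted p = 0.0969). This list was called downward (adjusted p = 0.00581; adjusted p = 0.58 with an estimated correlation). Of 20 senescence and p53 target genes, the urokinase receptor PLAUR rose (1.09 ± 0.235, adjusted p = 0.0454) and IGFBP7 fell (-1.16 ± 0.187, adjusted p = 0.0241), against 8 higher and 2 lower adjusted over the list alone. The list was called upward with an adjusted p of 0.00973 (adjusted p = 0.294 with an estimated correlation; 0.00838 by fry). None of 22 hypoxia and glycolysis genes passed over all genes, whereas 10 rose adjusted over the list alone. EGLN3 (1.20, adjusted p = 0.0748 over all genes) and NDRG1 (0.99, 0.0769) had the smallest p. Both passed by DESeq2 (0.00842 and 0.00901), with the replicate block (0.0266 and 0.0289), with the length and GC trend taken out (0.0466 and 0.0499) and without WT replicate 2 (0.0279 and 0.0254), within 0.00842 to 0.265 and 0.00901 to 0.269 over their alternatives. The hypoxia list was called upward (adjusted p = 2.55e-09; adjusted p = 0.58 with an estimated correlation). The lysosomal (adjusted p = 0.00713), oxidative phosphorylation (0.00123) and inflammatory (0.00973) lists were called upward and the cell cycle list (0.011) downward. For the inflammatory list WT replicate 1 had the highest score of these 6 libraries (0.853), against -0.3 and -0.553 in the other WT libraries and 0.15, 0.255 and 0.848 in HPS2. Cell cycle scores in HPS2 were -0.658, -0.368 and 0.199, so HPS2 replicate 3 lay above the highest WT library (0.096). None of their members passed by edgeR over all genes, and 3, 0, 0 and 0 did adjusted over the list alone. Of the lysosomal list, TFEB (0.79 ± 0.178, adjusted p = 0.0514) passed under 7 alternatives, the length and GC offset among them (0.0158, within 0.00214 to 0.195 over all). With an estimated correlation these lists had adjusted p = 0.58 for the first 3 and adjusted p = 0.592 for the cell cycle. Over all alternatives the adjusted p of the 8 lists ran from 4.31e-13 to 0.592. In 3 of the 10 splits of these 6 libraries camera called at least 8 lists.

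Calls in HPS2 against WT also rested on single libraries. Genes called numbered 0 without WT replicate 1 (1818 at an unadjusted p under 0.05), 0 without WT replicate 3 (1973), 0 without HPS2 replicate 2 (1889), 3 without HPS2 replicate 1, 24 without HPS2 replicate 3 and 300 without WT replicate 2. There were 275 higher and 366 lower with the length and GC trend taken out, among them 64 of the 64 and 88 of the 89, and 429 and 373 by the Wald test of DESeq2. The hypoxia list passed without any one library, whereas the transcription factor list was lost without WT replicate 2 (0.157) or WT replicate 3 (0.0771) and the mesenchymal list without WT replicate 3 (0.111). The inflammatory list was lost without WT replicate 2 (0.141), WT replicate 3 (0.215) or HPS2 replicate 3 (0.127) and with the length and GC trend taken out (0.0748). The senescence list was lost without WT replicate 2 (0.0665), the lysosomal list without HPS2 replicate 3 (0.0911), the cell cycle list without WT replicate 3 (0.0807) or HPS2 replicate 1 (0.533), and the oxidative phosphorylation list without WT replicate 3 (0.0771).

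The HPS8 line was compared with WT to describe a line of a subtype for which lung fibrosis is not known. The largest increase among the genes named was in C11orf86 (8.17 ± 1.19). Among the others were the apolipoproteins APOA4 (from 14.5 ± 4.13 to 3218 ± 2640 CPM, log2 change 7.80 ± 1.35, adjusted p = 0.00089), APOC3 (8.06 ± 1.36, adjusted p = 0.000763) and APOB (6.63 ± 1.3, adjusted p = 0.00175). The fatty acid-binding protein FABP1 rose from 14.9 ± 5.39 to 1377 ± 804 CPM (6.52 ± 1.04, adjusted p = 0.000558). ENPP7, vitronectin, VTN, and OSTBETA rose by 6.60 or more. HPS8 replicate 1 had the highest levels, with C11orf86 at 82.7, 9.57 and 32.2 CPM and APOB at 2552, 274.1 and 1028 CPM in HPS8 replicates 1, 2 and 3. Without it C11orf86, APOC3, APOA4, ENPP7, APOB, VTN and OSTBETA were at 7.21, 7.16, 6.96, 6.38, 5.69, 5.61 and 5.74 and still passed. C11orf86 was at 9 without WT replicate 2 and APOB at 7.37 without WT replicate 3. ZNF486 (-4.63), the basement membrane collagen COL4A3 (-4.35 ± 0.892, adjusted p = 0.00228), CYTL1, CRH, SPOCK3, PCP4, the growth factor receptor PDGFRA (-3.50 ± 0.684, adjusted p = 0.00175) and FILIP1 (-3.32) had the largest decreases. Without WT replicate 3 COL4A3, CRH, SPOCK3 and PDGFRA were at -3.01, -2.87, -3.11 and -2.55 and passed. ZNF486 (-4.02) and CYTL1 (-5.17) moved without HPS8 replicate 1, ZNF486 (-5.52) and CRH (-4.89) without HPS8 replicate 2, and SPOCK3 (-4.79) and PDGFRA (-4.15) without HPS8 replicate 3. In all, 2806 genes were higher and 2904 lower, 1622 and 1406 of them at least 2-fold, and 7264 had an unadjusted p under 0.05.

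Of 20 non-lung endoderm markers, 15 rose in HPS8 against WT, also 15 adjusted over the list alone. They included the hepatic and intestinal regulators HNF4A (3.11 ± 0.342, adjusted p = 0.000203) and CDX2 (5.10 ± 0.711, adjusted p = 0.000325) and the microvillar protein VIL1 (2.82 ± 0.403, adjusted p = 0.000337). The list was called by camera (adjusted p = 3.63e-07; adjusted p = 0.611 with an estimated correlation). The mean score of this list was also raised by 2.137 over WT in HPS2 replicate 3, against -0.541 and 0.12 in HPS2 replicates 1 and 2. Of 24 oxidative phosphorylation genes, 13 rose (16 adjusted over the list alone). Among them were UQCRC1 (1.33 ± 0.163, adjusted p = 0.000223) and NDUFA13 (1.35 ± 0.172), and the list adjusted p was 4.6e-07 (adjusted p = 0.611 with an estimated correlation). Of 25 lysosomal genes, 16 rose (17 higher and 1 lower adjusted over the list alone). TFEB (1.48 ± 0.18) and the hydrolases CTSA (2.78 ± 0.395) and CTSD (1.91 ± 0.277) were among them, with a list adjusted p of 2.4e-05 (adjusted p = 0.611 with an estimated correlation). Of 22 hypoxia and glycolysis genes, 11 rose, also 11 adjusted over the list alone (list adjusted p = 0.00333; adjusted p = 0.632 with an estimated correlation). The glycolytic enzymes ALDOC, TPI1 and ALDOA rose by 1.06 ± 0.221, 0.74 ± 0.164 and 0.93 ± 0.211. Of 25 interferon response genes, 8 rose and 2 fell (9 and 3 adjusted over the list alone). OAS1 rose by 3.59 ± 0.546, IFI35 by 2.08 ± 0.232 and ISG15 by 1.65 ± 0.218, while IFI44L fell by 1.91 ± 0.294 on the log2 scale. The list was called upward (adjusted p = 0.0281; adjusted p = 0.611 with an estimated correlation). Of 18 mesenchymal markers, 12 fell and ACTA2 rose, with the same counts adjusted over the list alone (list adjusted p = 0.00297; adjusted p = 0.611 with an estimated correlation). Decorin, DCN (-2.69 ± 0.541), CDH11 (-2.34), THY1 (-2.08) and PDGFRA were among those that fell. CDH11 was at -1.57 without WT replicate 3, CTSA at 2.18 without HPS8 replicate 1 and PDGFRA at -2.55 without WT replicate 3 and -4.15 without HPS8 replicate 3.

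HPS8 libraries differed from WT along transcript length and GC content. With that trend taken out, 2120 genes were higher and 2459 lower, of which 1557 (55.5% of the 2806) and 1490 (51.3% of the 2904) were among the first calls. ALDOC (0.47 ± 0.192, adjusted p = 0.083), TPI1 (0.07 ± 0.134, adjusted p = 0.723), ALDOA (0.53 ± 0.191, adjusted p = 0.051) and the oxidative phosphorylation genes CYC1 (0.37 ± 0.141 from 1.15 ± 0.168, adjusted p = 0.0621) and COX6B1 (0.33 ± 0.124 from 1.11 ± 0.181, adjusted p = 0.0603) no longer passed, because their changes shrank. Over their alternatives the adjusted p of these 5 genes ran from 8.29e-10 to 0.723. The interferon list was not called either (adjusted p = 0.195). The adjusted p of the 6 lists ran from 6.73e-10 to 0.632 over all alternatives. The count of lower genes was 1924 without HPS8 replicate 2 and 1906 without HPS8 replicate 3. The interferon list was also lost without WT replicate 3 (0.0503), HPS8 replicate 2 (0.0578) or HPS8 replicate 3 (0.0741).

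**Figure D3:**
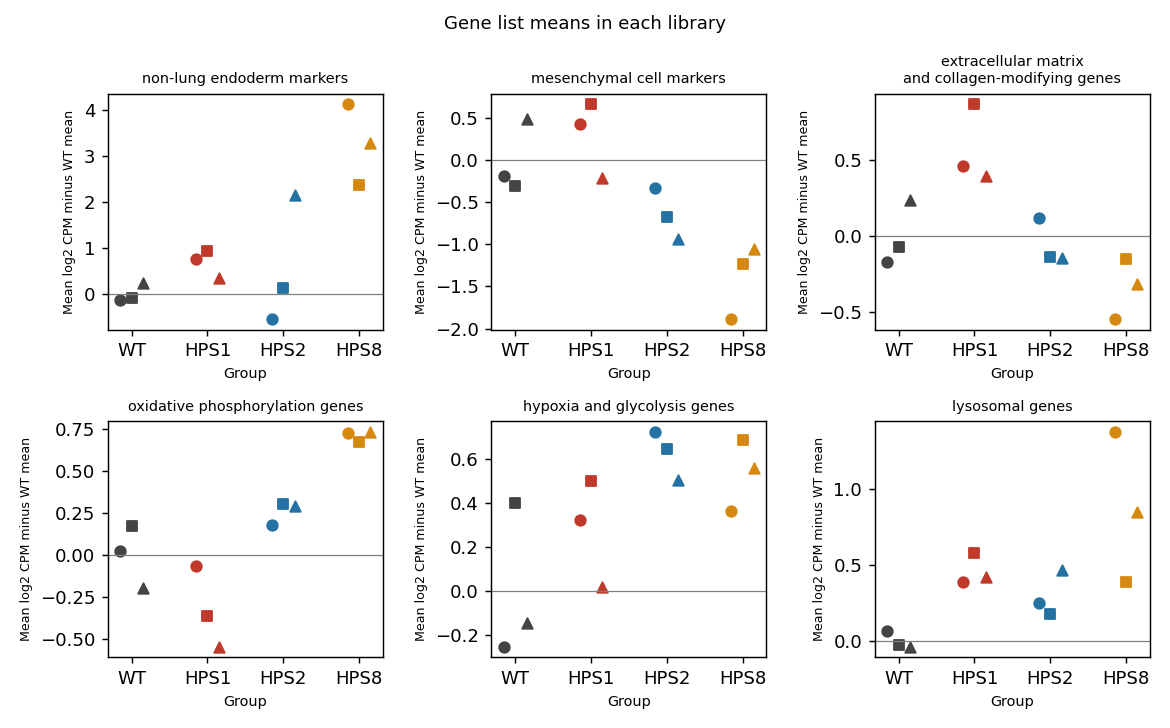
Mean log2 CPM of the genes of each of 6 fixed lists minus the WT mean (y axes), for the 3 libraries of each group (x axes), with circles, squares and triangles for replicates 1, 2 and 3. The HPS8 libraries lie at 2.361 to 4.115 for non-lung endoderm markers, and HPS2 replicate 3 at 2.137.

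To ask which changes were common to the lines of the subtypes with fibrosis, the calls of HPS1 and HPS2 against WT were overlapped. They shared 19 higher genes and 12 lower genes, where independent lists would share 0.861 and 0.906, and 0 genes went in opposite directions. With the length and GC trend taken out, 7 of the 19 and 5 of the 12 were still shared. None was shared without WT replicate 1, WT replicate 3, HPS1 replicate 2 or HPS2 replicate 2. Of the genes higher in both, 3 were also higher in both than in HPS8. The transcription factor PROX1 was at 17.8 ± 2.59 CPM in HPS1, 17.1 ± 2.58 in HPS2, 8 ± 1.39 in HPS8 and 7.22 ± 1.61 in WT. The exocytosis-associated small GTPase RAB3B was at 87.5 ± 20.1, 76.5 ± 10.4, 43.4 ± 1.18 and 38.7 ± 1.36 CPM in the same order. The sorting receptor SORL1 was at 173.4 ± 12.3, 194.4 ± 25.7, 118.1 ± 3.06 and 109.5 ± 13.5 CPM. Against WT, PROX1 rose by 1.31 ± 0.24 and 1.24 ± 0.239 in HPS1 and HPS2 (adjusted p = 0.0226 and 0.0328). RAB3B rose by 1.18 ± 0.186 and 0.99 ± 0.185 (adjusted p = 0.0175 and 0.0306) and SORL1 by 0.66 ± 0.163 and 0.83 ± 0.163 (adjusted p = 0.0483 and 0.0359). None of the 3 passed in HPS8 against WT (adjusted p of 0.651, 0.499 and 0.624), although PROX1 and RAB3B did with a length and GC trend taken out (0.0157 and 0.0158, within 0.0157 to 0.962 and 0.0158 to 0.651 over their alternatives). No gene was lower in both lines than in both WT and HPS8 in the main fit of edgeR. There were 3 by DESeq2, and by edgeR 1 with the replicate block and 1 without HPS8 replicate 2. The 4 comparisons had 3495, 2672, 6763 and 5668 genes at an unadjusted p under 0.05 by edgeR.

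HPS8 shared more calls with each of the other lines: 104 higher and 83 lower with HPS1 (37.8 and 29.5 for independent lists, with 10 and 8 in opposite directions) and 57 higher and 72 lower with HPS2 (11.8 and 17, with 0 opposite). All of these comparisons used the same WT libraries. Across genes, which are not independent replicates, the changes of HPS1 and HPS2 against WT correlated at r = 0.429, those of HPS1 and HPS8 at 0.423 and those of HPS2 and HPS8 at 0.664. Unchanged groups simulated against shared controls, without any pairing by replicate number, gave 0.489, 0.494 and 0.493. The covariances were 0.161, 0.281 and 0.425 against simulated values of 0.0628, 0.0632 and 0.0622. At most 0 genes were called in common in the simulation. No gene was changed in it, so this count does not measure how shared controls affect the overlap of lists of changed genes. Counts were drawn separately for each gene, without shifts of a whole library. The 3 WT libraries cannot be split with at least 2 on each side, so the part owed to shared controls was not measured on the libraries.

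The set of 3 genes depended on the libraries and on the trend with length and GC content. It was 0 without any one of WT replicates 1, 2 and 3, HPS1 replicate 2, HPS2 replicates 1 and 2 or HPS8 replicate 3. The criteria gave 1 gene, none of the 3, without HPS2 replicate 3, and 2 genes, both among the 3, without HPS8 replicate 1. They gave 4 genes without HPS1 replicate 1 (3 of the 3) or HPS1 replicate 3 (2 of the 3), and 5 without HPS8 replicate 2 (3 of the 3). With the trend taken out it held 5 genes and 0 of these 3. PROX1 and RAB3B still passed against WT in both lines. They then rose in HPS8 against WT as well, PROX1 by 0.82 ± 0.225 (from 0.15 ± 0.239) and RAB3B by 0.64 ± 0.176 (from 0.17 ± 0.184). Against HPS8, the HPS2 line then differed by 0.53 ± 0.221 in PROX1 (from 1.10 ± 0.238; adjusted p = 0.122, 0.000292 to 0.122 over its alternatives) and 0.41 ± 0.174 in RAB3B (from 0.82 ± 0.184; adjusted p = 0.128, 0.000655 to 0.128). SORL1 passed neither against HPS8 (0.14 ± 0.152 from 0.55 ± 0.163 in HPS1, and 0.45 ± 0.152 from 0.72 ± 0.163 in HPS2) nor in HPS1 against WT (0.56 ± 0.152, adjusted p = 0.0867, 0.00212 to 0.263).

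**Figure D4:**
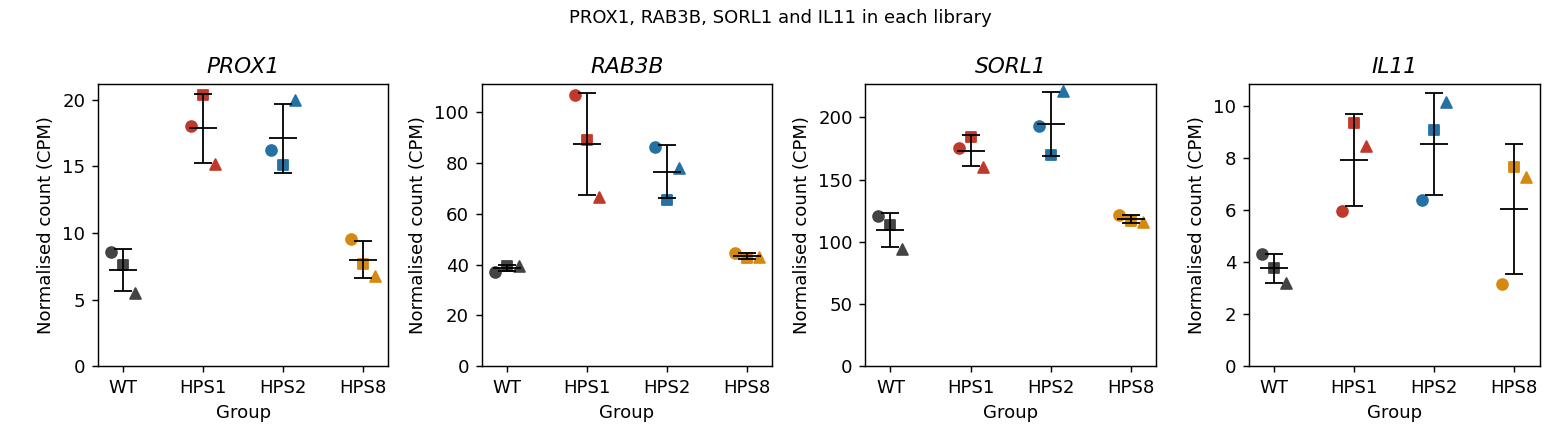
CPM (y axes, from 0) of PROX1, RAB3B, SORL1 and IL11 in the 3 libraries of each group (x axes), with circles, squares and triangles for replicates 1, 2 and 3, a bar at the group mean and error bars of 1 SD. PROX1 averages 17.8 CPM in HPS1 and 17.1 CPM in HPS2, against 8 CPM in HPS8 and 7.22 CPM in WT.

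The direct comparison of HPS1 with HPS8 asks what sets the type 1 line apart from the line of the subtype for which fibrosis is not known. DLK1, a Notch-related surface protein (4.42 ± 0.652, adjusted p = 0.000464), ZNF486 (4.32), ZNF469 (3.63) and GZMM (3.56) were the genes most raised in HPS1, and C11orf86 (-7.30 ± 1.14), APOA4 (-6.78 ± 1.29), APOC3 (-6.71 ± 1.27) and FMO1 (-6.64) those most lowered. Without HPS8 replicate 1 ZNF486, ZNF469, C11orf86, APOA4, APOC3 and FMO1 were at 3.70, 3.00, -6.37, -5.96, -5.81 and -5.99, and without HPS8 replicate 2 ZNF486 and ZNF469 were at 5.23 and 4.60. GZMM was at 2.92 without HPS1 replicate 3 and C11orf86 at -8.21 without HPS1 replicate 1. Collagen COL1A1 was higher in HPS1 (1.46 ± 0.303, adjusted p = 0.00293), as was vimentin, VIM (0.69 ± 0.217, adjusted p = 0.0256), and BLOC1S3 was higher by 0.88 ± 0.266 (adjusted p = 0.022). The HPS1 gene was lower in the HPS1 line than in the HPS8 line (-1.49 ± 0.191, adjusted p = 0.000248). In all, 2523 genes were higher and 2478 lower, 1165 and 1526 of them at least 2-fold.

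In that comparison 12 of 18 mesenchymal markers were higher in HPS1 (13 adjusted over the list alone). Camera called the list (adjusted p = 1.57e-05, and adjusted p = 0.389 with an estimated correlation). Of 23 extracellular matrix genes, 13 were higher and 1 lower in HPS1 (16 and 1 adjusted over the list alone; adjusted p = 2.62e-05 and adjusted p = 0.389 with an estimated correlation). Of 21 genes of the transforming growth factor beta pathway, 6 were higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.0195 and adjusted p = 0.338 with an estimated correlation). In the other direction, 20 of 24 oxidative phosphorylation genes were lower in HPS1 (21 adjusted over the list alone; adjusted p = 3.48e-11 and adjusted p = 0.338 with an estimated correlation). So were 14 of 20 non-lung endoderm markers (17 adjusted over the list alone; adjusted p = 9.94e-07 and adjusted p = 0.457 with an estimated correlation). Of 12 airway basal cell markers, 4 were lower (4 adjusted over the list alone; adjusted p = 0.0457 and adjusted p = 0.409 with an estimated correlation). Of 25 interferon response genes, 10 were lower and 1 higher, likewise adjusted over the list alone (adjusted p = 0.0261 and adjusted p = 0.338 with an estimated correlation). Over all alternatives the adjusted p of the 7 lists ran from 1.55e-14 to 0.457. The count of higher genes was 1404 without HPS8 replicate 3. The basal list was lost without HPS1 replicate 1 (0.131), HPS8 replicate 1 (0.0596) or HPS8 replicate 3 (0.0506), the interferon list without HPS1 replicate 1 (0.0535) or HPS8 replicate 3 (0.0506), and the transforming growth factor beta list without HPS8 replicate 1 (0.0549). BLOC1S3 was lost without HPS1 replicate 2 (0.0928), HPS8 replicate 2 (0.0748) or HPS8 replicate 3 (0.097). VIM was lost without HPS1 replicate 2 (0.057), HPS1 replicate 3 (0.0948), HPS8 replicate 1 (0.0624), HPS8 replicate 2 (0.0623) or HPS8 replicate 3 (0.0942). SORL1 was lost without HPS1 replicate 2 (0.0647), HPS8 replicate 1 (0.0574) or HPS8 replicate 3 (0.0945). With the length and GC trend taken out, 2785 genes were higher and 2553 lower, of which 1937 and 1737 were among the first calls. The interferon list was then lost (0.248).

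The same question was put to type 2 by comparing HPS2 with HPS8. The adhesion molecule CHL1 (3.25 ± 0.728, adjusted p = 0.00917) and the colony-stimulating factor CSF3 (2.81 ± 0.866, adjusted p = 0.0334) were higher in HPS2. CHL1 had 19.5, 6.26 and 1.28 CPM in HPS2 replicates 1, 2 and 3 and at most 1.28 CPM in HPS8, and was at 1.95 without HPS2 replicate 1 (adjusted p = 0.0556). The ephrin receptor EPHA3 (2.39 ± 0.457, adjusted p = 0.00519) and PLEKHH2 (2.36 ± 0.409, adjusted p = 0.00421) followed. The intestinal anion exchanger SLC26A3 (-5.58 ± 1.1, adjusted p = 0.00578), FAM151A (-5.17), LAPTM5 (-4.83 ± 0.483, adjusted p = 0.000586) and the secretin receptor SCTR (-4.66 ± 1.26, adjusted p = 0.0195) were lowest. Without HPS8 replicate 1 SLC26A3, FAM151A and SCTR were at -4.54, -4.03 and -3.49, and without HPS2 replicate 3 SCTR was at -5.77 and CSF3 at 2.20. SLC26A3 (0, 0 and 1.17 CPM) and FAM151A (0, 0.0688 and 0.533 CPM) had nearly all their HPS2 counts in replicate 3, so the sizes of their changes rested on that library. AP3B1 was lower in HPS2 than in HPS8 (-0.85 ± 0.246, adjusted p = 0.0266), as was the HPS1 gene (-0.56 ± 0.187, adjusted p = 0.0448). In all, 1684 genes were higher and 1633 lower, 716 and 840 of them at least 2-fold.

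The 3 lists called in HPS2 against HPS8 went down. Of 20 non-lung endoderm markers, 12 were lower (14 adjusted over the list alone; adjusted p = 1.33e-08), as were 7 of 24 oxidative phosphorylation genes (7 adjusted over the list alone; adjusted p = 5.4e-05). Of 25 lysosomal genes, 13 were lower (14 lower and 2 higher adjusted over the list alone; adjusted p = 0.000494). Each had an adjusted p = 0.847 with an estimated correlation. For the 3 lists the adjusted p ran from 1.34e-13 to 0.847 over all alternatives. With the length and GC trend taken out, 1029 genes were higher and 1010 lower, of which 617 and 698 were among the first calls. The HPS1 gene did not pass (-0.15 ± 0.138, adjusted p = 0.512). The numbers of higher and lower genes were 585 and 697 without HPS2 replicate 1, 867 and 713 without HPS2 replicate 2, 1048 and 1269 without HPS8 replicate 1, 869 and 1348 without HPS8 replicate 2, and 794 and 1114 without HPS8 replicate 3. CSF3 (0.0518 to 0.101) and the HPS1 gene (0.0664 to 0.114) were lost without any one of the 6 libraries. SCTR was lost without HPS2 replicate 1 (0.074), HPS2 replicate 2 (0.065) or HPS8 replicate 1 (0.0676). AP3B1 was lost without HPS2 replicate 2 (0.103), HPS8 replicate 1 (0.0682) or HPS8 replicate 3 (0.0698).

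HPS1 and HPS2 were compared with each other, since a change can be called particular to 1 of these lines only if they differ directly. TTYH1 (3.29 ± 0.425, adjusted p = 0.00449), MCAM (2.67 ± 0.582, adjusted p = 0.0192), GZMM (2.56, adjusted p = 0.0194) and the basement membrane protein nidogen-2, NID2 (2.51 ± 0.488, adjusted p = 0.0149), were higher in HPS1. Lipocalin-2, LCN2, was lower, at 13.2 ± 3.71 CPM in HPS1 and 91.4 ± 17.1 CPM in HPS2 (-2.79 ± 0.383, adjusted p = 0.00468). C9orf64 (-3.64 ± 0.616, adjusted p = 0.00945), the nucleoside transporter SLC28A3 (-2.52) and EYS (-2.26) were lower. MCAM and GZMM were at 1.81 and 1.92 without HPS1 replicate 3, and GZMM and EYS at 3.26 and -1.30 without HPS2 replicate 3. AP3B1 was higher in HPS1 (1.29 ± 0.249, adjusted p = 0.0146) and the HPS1 gene lower (-0.92 ± 0.189, adjusted p = 0.0164). COL1A1 (1.23 ± 0.301, adjusted p = 0.0269) and surfactant protein B, SFTPB (1.13 ± 0.331, adjusted p = 0.0496), were higher in HPS1. In all, 686 genes were higher and 601 lower, 353 and 271 of them at least 2-fold.

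Between HPS1 and HPS2, 8 of 23 extracellular matrix genes were higher in HPS1 (11 higher and 1 lower adjusted over the list alone; adjusted p = 1.63e-05). Of 18 mesenchymal markers, 3 were higher (9 adjusted over the list alone; adjusted p = 2.35e-05). In contrast, 11 of 24 oxidative phosphorylation genes were lower (16 lower and 1 higher adjusted over the list alone; adjusted p = 8.6e-08). These gave adjusted p = 0.545 with an estimated correlation. Of 22 hypoxia and glycolysis genes, ANKRD37, chosen after its value was seen, was lower, 1 also adjusted over the list alone (list adjusted p = 0.0232; adjusted p = 0.777 with an estimated correlation). Over all alternatives the adjusted p of the 4 lists ran from 1.25e-08 to 0.777. The hypoxia list was lost without HPS1 replicate 1 (0.0553), HPS1 replicate 3 (0.129) or HPS2 replicate 1 (0.0924). The number of genes called was 14 without HPS1 replicate 2, 23 without HPS2 replicate 2, 110 without HPS2 replicate 1, 228 without HPS1 replicate 3, 1364 without HPS2 replicate 3 and 3059 without HPS1 replicate 1. It was 225 higher and 156 lower with these 2 groups alone in the fit. TTYH1 and LCN2 passed without any one library. COL1A1 was lost without HPS1 replicate 2 (0.126), HPS1 replicate 3 (0.0679), HPS2 replicate 1 (0.0848) or HPS2 replicate 2 (0.118). SFTPB was lost without HPS1 replicate 2 (0.104), HPS1 replicate 3 (0.53, adjusted p = 0.229), HPS2 replicate 1 (0.119), HPS2 replicate 2 (0.164) or HPS2 replicate 3 (0.0735). MCAM, GZMM, NID2, C9orf64, SLC28A3, EYS, AP3B1 and the HPS1 gene were each lost without HPS1 replicate 2 (0.0657 to 0.135) or HPS2 replicate 2 (0.0522 to 0.0941). MCAM (0.0719), GZMM (0.0728) and EYS (0.107) were also lost without HPS1 replicate 3, and MCAM (0.0779), GZMM (0.0798), NID2 (0.0615), EYS (0.0615) and the HPS1 gene (0.0567) without HPS2 replicate 1. EYS (0.112) was also lost without HPS2 replicate 3. With the length and GC trend taken out, 677 genes were higher and 734 lower, of which 419 and 398 were among the first calls. COL1A1 (0.75 ± 0.23, adjusted p = 0.0571) and SFTPB (0.85 ± 0.28, adjusted p = 0.07) then did not pass, within 0.00138 to 0.126 and 0.00759 to 0.229 over their alternatives.

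Genes fixed beforehand for every comparison included interleukin 11, IL11, a cytokine studied in fibrosis. IL11 was at 7.93 ± 1.77 CPM in HPS1, 8.55 ± 1.96 in HPS2, 6.05 ± 2.49 in HPS8 and 3.77 ± 0.553 in WT. It did not pass in HPS1 (log2 change 1.07 ± 0.341, adjusted p = 0.0955), HPS2 (1.18 ± 0.339, adjusted p = 0.1) or HPS8 (0.68 ± 0.338, adjusted p = 0.126). By the Wald test of DESeq2 it passed in HPS1 (adjusted p = 0.0332, 0.0332 to 0.368 over its alternatives) and HPS2 (0.0247, 0.0247 to 0.291). In HPS8 it passed without HPS8 replicate 1 (0.0197, 0.0197 to 0.71). COL1A1 was at 713 ± 190 CPM in HPS1 and 353.7 ± 134 in WT without passing (1.01 ± 0.3, adjusted p = 0.0785). It also did not pass in HPS2 (-0.22, adjusted p = 0.736) or HPS8 (-0.45, adjusted p = 0.251). COL1A1 passed in HPS1 by the Wald test of DESeq2 (0.0176) and without HPS1 replicate 1 (0.0286), within 0.0176 to 0.36 over its alternatives. In HPS8 it passed with the length and GC trend taken out (-0.77 ± 0.23, adjusted p = 0.0232, within 0.0232 to 0.833). VIM fell in HPS8 (-1.11 ± 0.219, adjusted p = 0.00184). It did not pass in HPS1 (-0.42, adjusted p = 0.262) or HPS2 (-0.57, adjusted p = 0.198). SFTPB did not pass in HPS1 (-0.07, adjusted p = 0.915), HPS2 (-1.19 ± 0.331, adjusted p = 0.0938) or HPS8 (-0.32, adjusted p = 0.455). In HPS2 it passed by the Wald test of DESeq2 (0.0166), with only these 2 groups in the fit (0.0315) and with the length and GC trend taken out (0.0347), within 0.0166 to 0.289 over its alternatives. EPCAM, the marker of the sort, was at 489.8, 410.5, 447.3 and 457.6 CPM in HPS1, HPS2, HPS8 and WT. It passed against WT in none of the lines (adjusted p of 0.808, 0.739 and 0.917). With the length and GC trend taken out it was higher in HPS1 than in HPS8 (0.58 ± 0.145 from 0.13 ± 0.215, adjusted p = 0.00817, within 0.00817 to 0.938 over its alternatives) and HPS2 (0.59 ± 0.145 from 0.25 ± 0.215, adjusted p = 0.0295, within 0.0295 to 0.706). Surfactant protein C, SFTPC, had group means of at most 0.0663 CPM, too few counts to be tested, so a difference was not detectable at this depth.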

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

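The tests of all patterns in this part were chosen only after the result was seen, whereas the splits of the libraries were planned. Some fixed gene lists had a median change against WT of one sign in 1 edited line and of the opposite sign in another, and differed between the 2 lines by camera in their direct comparison.

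Between HPS1 and HPS8 there were 6 such lists. Mesenchymal cell markers had medians of 0.33 and -1.67 against WT (adjusted p = 1.57e-05 for the difference; adjusted p = 0.389 with an estimated correlation), and extracellular matrix genes 0.63 and -0.38 (adjusted p = 2.62e-05; adjusted p = 0.389 with an estimated correlation). Genes of the transforming growth factor beta pathway had medians of 0.03 and -0.63 (adjusted p = 0.0195; adjusted p = 0.338 with an estimated correlation). Oxidative phosphorylation genes had medians of -0.40 and 0.60 (adjusted p = 3.48e-11; adjusted p = 0.338 with an estimated correlation), airway basal cell markers -0.18 and 0.58 (adjusted p = 0.0457; adjusted p = 0.409 with an estimated correlation) and interferon response genes -0.12 and 0.65 (adjusted p = 0.0261; adjusted p = 0.338 with an estimated correlation). In HPS1 against WT the transforming growth factor beta, basal and interferon lists were not called (camera adjusted p of 0.683, 0.798 and 0.959). Their opposite signs rest on medians near 0 in that line, and the camera direction of the interferon list was upward. Mesenchymal markers were not called in HPS1 against WT either (0.0846). In HPS8 against WT the matrix (0.41), transforming growth factor beta (0.108) and basal (0.108) lists were not called. Only oxidative phosphorylation genes were called against WT in both lines. In HPS1 that call was lost with the length and GC trend taken out and without WT replicate 2, as given above. HPS1 replicate 1 had a list score of -0.064, within the WT range of -0.198 to 0.173.

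Between HPS1 and HPS2 there were 3, each also among those 6. Oxidative phosphorylation genes had medians of -0.40 and 0.28 against WT (adjusted p = 8.6e-08), extracellular matrix genes 0.63 and -0.15 (adjusted p = 1.63e-05) and mesenchymal markers 0.33 and -0.62 (adjusted p = 2.35e-05), each with adjusted p = 0.545 with an estimated correlation. In HPS2 against WT the matrix list had a negative median but an upward camera direction, without a call (adjusted p = 0.98). The mesenchymal list was not called by camera in HPS1 against WT (adjusted p = 0.0846).

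Non-lung endoderm markers were higher in HPS8 than in WT, with a median log2 change of 4.02 (95% bootstrap interval over members 2.24 to 5.04). Here and below, such intervals treat the members of a list as independent and leave out the spread between libraries. They do not show whether a change exceeds that spread. A trend on transcript length and GC content was argued against as the whole cause, since the median was 3.845 (2.12 to 4.45) with that trend taken out. Mesenchymal markers had a median of -1.669 (-2.21 to -0.81), so no rise of mesenchymal transcripts was seen in HPS8. The non-lung endoderm markers are largely those of epithelial cells of other organs, so a lower share of epithelial cells need not raise them. The mesenchymal values therefore do not decide whether that share played a part. The course of the differentiation rather than the genotype stays open: HPS2 replicate 3, outside HPS8, had a mean list score of 2.137 over WT, close to the lowest HPS8 library at 2.361, the HPS1 libraries (0.344 to 0.938) lay above the highest WT library (0.229), and the design holds 1 line per genotype. The HPS8 mutation itself also stays open and was not tested apart from the line.

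Extracellular matrix genes were higher in HPS1 than in WT, with a median of 0.63 (0.38 to 0.68). With the length and GC trend taken out in the fit with the replicate block, the median was 0.362 (0.29 to 0.62). Camera then gave an adjusted p of 1.48e-05, within 2.27e-09 to 0.695 over the alternatives. Over the members, these values argued against that trend as the whole cause, without regard to the spread between libraries. Mesenchymal cells carried through the EPCAM sort could not be excluded: mesenchymal markers outside the matrix list had a median of 0.206, and its interval of -0.18 to 0.47 holds 0 and lies below the matrix median, but overlaps the lower part of the matrix interval. A response of the epithelial cells to the type 1 mutation stays open beside it, so the source of the matrix transcripts in HPS1 could be either.

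Oxidative phosphorylation genes were lower in HPS1 than in HPS2, with a median of -0.71 (-0.85 to -0.41). With the length and GC trend taken out, the median was -0.291 (-0.48 to -0.14). Camera then gave an adjusted p of 0.00136, within 1.25e-08 to 0.545 over the alternatives. That trend could have contributed. Over the members, the values argued against it as the whole cause, without regard to the spread between libraries. The difference between the genotypes stays open, untested apart from differences between the lines or the differentiations.

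Other splits of the 6 libraries of a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. Each other split put libraries of both groups on both sides, so a difference between the groups widens the spread within sides and lowers the counts. The gap between real and other counts of genes therefore does not measure how strong a difference is. Real and highest other counts of genes were 360 and 1 for HPS1 against WT, 153 and 0 for HPS2 against WT, 5710 and 0 for HPS8 against WT, 5001 and 0 for HPS1 against HPS8, 3317 and 0 for HPS2 against HPS8, and 1287 and 1 for HPS1 against HPS2, so 1 split, the real one, gave as many in each. For gene lists, the real and highest other counts were 5 and 11, 8 and 12, 6 and 9, 7 and 10, 3 and 10, and 4 and 9 in the same order, with 7, 3, 6, 4, 8 and 9 splits giving as many. Over 100 regroupings of the 12 libraries into 4 groups of 3, the 31 genes called in the same direction in HPS1 and HPS2 against WT were matched by 1, the real grouping, with 0 as the highest other, and the 3 genes of both lines against both WT and HPS8 likewise by 1, with 0 as the highest other. Because those groupings spread the distant HPS8 libraries over other groups, which widens the spread within groups, they do not decide whether HPS1 and HPS2 share changes. Both counts were 0 without WT replicate 1, WT replicate 3, HPS1 replicate 2 or HPS2 replicate 2. Without WT replicate 2 they were 6 higher and 3 lower genes and 0, without HPS2 replicate 1 they were 1 higher and 0 lower and 0, without HPS2 replicate 3 they were 4 higher and 1 lower and 1, and without HPS8 replicate 3 the second was 0. Without HPS1 replicate 1 the first was 30 higher and 19 lower and without HPS1 replicate 3 it was 38 and 31, and the second was 5 higher and 1 lower without HPS8 replicate 2.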

How the results depend on the processing

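Alternatives chosen only after the results were seen were the length and GC offset, alone or with the replicate block, and camera with DESeq2 size factors. Of 132 called results for named genes other than the targeted ones, 0 turned in direction under any alternative; the size factors of DESeq2 in edgeR, its Wald test and the replicate block lost 0 of these calls, no filter on low counts lost 1, the fit of 2 groups alone lost 13 and the length and GC offset lost 27. Leaving out 1 library lost from 0 of 53 (HPS1 replicate 1) to 40 of 51 (HPS2 replicate 2), with 39 of 53 for HPS1 replicate 2, 37 of 51 for HPS2 replicate 1 and 52 of 92 for WT replicate 3. The cause was not tested for any of the changes below, except that a fit with 1 library or 2 groups fewer has less information on the spread. At these depths edgeR found 33 of 100 simulated 2-fold changes in HPS1 against WT, so 2-fold changes were often missed.

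By the Wald test of DESeq2 there were 779 higher and 527 lower genes in HPS1 against WT, 429 and 373 in HPS2 against WT, 1356 and 1039 in HPS1 against HPS2, 125 and 84 shared by HPS1 and HPS2 against WT, and 12 and 3 in both lines against both WT and HPS8. No filter on low counts gave 129 and 147 in HPS2 against WT and 38 and 24 shared with HPS1. Only the 2 groups in the fit gave 225 and 156 in HPS1 against HPS2, and AP3B1 in HPS2 against WT did not pass (-1.31, adjusted p = 0.051). The length and GC offset gave 77 and 40 in HPS1 against WT, 275 and 366 in HPS2 against WT, 1029 and 1010 in HPS2 against HPS8, and 5 higher genes in both lines against both WT and HPS8. With this offset the HPS1 gene passed in HPS1 against WT (-0.99, adjusted p = 0.0136), as with the offset and the block (-0.99, adjusted p = 0.0233), which gave 45 higher and 15 lower genes, 31 and 9 of them among the first calls. The offset with the block lost 18 of 26 calls for named genes in HPS1 against WT; beyond those lost with the offset alone these were TSPAN18 (2.41, adjusted p = 0.0726, within 3.87e-06 to 0.162 over its alternatives), OAS3 (-3.70, 0.0674, within 0.00119 to 0.213) and PTGER3 (-1.88, 0.0555, within 1.1e-05 to 0.17).

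The replicate block gave 347 higher and 255 lower genes in HPS1 against WT, where the numbers were taken to pair the libraries, and changed no call of a gene list there; it made 5 calls for named genes, PRSS8 (0.0482), P4HA2 (0.0426), COL6A1 (0.0439), GAA (0.0325) and CA9 (0.038), and lost none. In the other comparisons the correlations of same-numbered deviations were not all over 0.1 (-0.1343, 0.2613 and -0.01858 in HPS2 against WT). In every comparison, HPS1 against WT included (replicate 1), at least 1 number did not correlate best with itself. There the block gave 179 and 177 in HPS2 against WT, 50 and 39 shared by HPS1 and HPS2, and 6 and 1 in both lines against both WT and HPS8.

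Directions that reversed belonged to results that did not pass. AP3B1 in HPS1 against WT was 0.31 with the length and GC offset and 0.31 with the block as well, ST14 was -0.0144 and -0.0168, and COX6A1 was 0.20 and 0.18; AP3B1 in HPS8 against WT was 0.21 with the offset, and EPCAM in HPS8 against WT was 0.0085 with at least 5 CPM in 3 libraries. Leaving out 1 library gave ranges of -0.32 to 0.0603 for BLOC1S3, -0.22 to 0.17 for EPCAM and -0.0208 to 0.29 for PROX1 in HPS8 against WT; -0.12 to 0.10 for AP3B1, -0.67 to 0.23 for SFTPB and -0.0107 to 0.21 for EPCAM in HPS1 against WT; and -0.37 to 0.14 for COL1A1 in HPS2 against WT. Ranges were -0.34 to 0.55 for SFTPB and -0.0503 to 0.31 for EPCAM in HPS1 against HPS8, -0.33 to 0.0576 for EPCAM and -0.0376 to 0.52 for COL1A1 in HPS2 against HPS8, and -0.29 to 0.0599 for IL11 and -0.0362 to 0.31 for VIM in HPS1 against HPS2. AP3B1 in HPS2 against WT ranged from -1.59 to -1.06 and did not pass without WT replicate 1 (0.126) or 3 (0.102) or HPS2 replicate 1 (0.052), 2 (0.0853) or 3 (0.0733).

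Leaving out 1 library gave 0 (without WT replicate 3 or HPS1 replicate 2) to 1173 (without HPS1 replicate 1) higher and 0 to 1138 lower genes in HPS1 against WT, and 0 (without WT replicate 1, WT replicate 3 or HPS2 replicate 2) to 142 (without WT replicate 2) higher and 0 to 158 lower genes in HPS2 against WT; at the counts of 0 from edgeR, 1818 to 2842 genes had an unadjusted p under 0.05, and DESeq2 was not run without single libraries. Lower genes in HPS8 against WT ranged from 1906 (without HPS8 replicate 3; 1924 without HPS8 replicate 2) to 2600 (without WT replicate 2). Ranges were 1404 (without HPS8 replicate 3) to 2311 higher genes in HPS1 against HPS8, 585 to 1568 higher and 697 to 1674 lower in HPS2 against HPS8 (without HPS2 replicate 1 and HPS2 replicate 3), and 9 to 1618 higher and 5 to 1441 lower in HPS1 against HPS2 (without HPS1 replicate 2 and HPS1 replicate 1). Genes shared by HPS1 and HPS2 against WT ranged from 0 to 38 higher and 0 to 31 lower (without WT replicate 1 and HPS1 replicate 3), and those in both lines against both WT and HPS8 from 0 to 5 higher and 0 to 1 lower (without WT replicate 1 and HPS8 replicate 2).

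For the lists, an estimated correlation gave 0 calls in each of the 6 comparisons; fry gave 0 in HPS1 against WT, 1 in HPS2 against WT, 17 in HPS8 against WT and 0 in HPS1 against HPS2. The length and GC offset gave 9 in HPS1 against WT (8 with the block) and 7 in HPS2 against HPS8. Leaving out 1 library gave 3 (without HPS1 replicate 2) to 9 (without HPS1 replicate 3) called lists in HPS1 against WT, 3 (without WT replicate 3) to 11 (without HPS2 replicate 2) in HPS2 against WT and 3 (without HPS2 replicate 2) to 6 (without HPS2 replicate 3) in HPS2 against HPS8.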

Other observations

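The test of chromosome shifts after the length and GC offset was chosen only after the result was seen, while the bounds on the shifts themselves were planned. Genes named in the next 2 paragraphs were chosen after their values were seen.

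Lists that were not called as a whole in HPS8 against WT held genes that moved in both directions. Of 22 inflammatory cytokines and chemokines, 5 rose and 9 fell: IL8 (-2.94 ± 0.672, adjusted p = 0.00416), CXCL3 (-2.19 ± 0.544, adjusted p = 0.00661) and ICAM1 (-1.43 ± 0.316, adjusted p = 0.00348) fell and IL32 rose (1.16 ± 0.225, adjusted p = 0.00165), with IL8 at 108.8 ± 123 CPM in the 3 WT libraries. Among 18 alveolar type 2 cell markers, PGC (1.89 ± 0.29), CEBPA (3.08) and CTSH (1.76) were the 3 that rose, and SFTA3 (-1.51 ± 0.216) was 1 of 4 that fell. Among 16 alveolar type 1 markers, CLIC5 rose (3.30 ± 0.716), and PDPN (-1.45) and RTKN2 (-1.30) were among 6 that fell. Of 17 genes of complexes mutated in Hermansky-Pudlak syndromes or acting with them, 4 rose, including HPS6 (1.74 ± 0.261) and BLOC1S1 (1.74 ± 0.271), and 2 fell, HPS3 (-0.74) and AP3M1 (-0.87).

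In HPS1 against WT, 3 of 11 airway secretory cell genes fell, the secretoglobin SCGB3A2 (-2.29), TFF3 (-2.61) and LCN2 (-1.69), in a list with a median of 0.0033, a mean of -0.45 and a downward camera test without a call (adjusted p = 0.0846). The cytokine TGFB1 (1.33 ± 0.262, adjusted p = 0.0258) rose, as did the Wnt feedback gene NKD1 (1.60 ± 0.285, adjusted p = 0.0203) and HNF4A (1.54 ± 0.327, adjusted p = 0.0321), and the cell cycle inhibitor gene CDKN2A fell (-1.35 ± 0.321, adjusted p = 0.044). Of 21 genes of the transforming growth factor beta list, TGFB1 among them, 2 rose, and camera did not call the list (median 0.033, adjusted p = 0.683). All these calls in HPS1 were lost without WT replicate 3 or HPS1 replicate 2, where edgeR called no gene. In HPS2 against WT, the interleukin 6 receptor IL6R rose (1.55 ± 0.34, adjusted p = 0.0466) and BAMBI fell (-0.99 ± 0.215, adjusted p = 0.046). Both calls were lost without WT replicate 1, WT replicate 3 or HPS2 replicate 2, where edgeR called no gene.

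As a hypothesis, a line could have gained or lost a whole chromosome in culture or editing, which would shift the median of that chromosome's genes. The bound set in advance was an interval wholly beyond 0.3 on the log2 scale for any of the 22 autosomes. The largest shifts were -0.251 in HPS1 and -0.114 in HPS2, both on chromosome 13 and within the bound. In HPS8 the bound was exceeded, with -0.422 (95% bootstrap interval -0.504 to -0.302) on chromosome 13 and 0.393 (0.339 to 0.464) on chromosome 19, so by that bound alone a chromosome change would have been accepted. Chromosomes 4 (-0.321) and 22 (0.311) shifted too. With the length and GC trend taken out, the largest shift in HPS8 was -0.077 (chromosome 7), with 0.011 on chromosome 19 and -0.071 on chromosome 13. A change in the number of 1 chromosome should largely pass through an offset fitted over the genes of all chromosomes, so a length and GC trend is a likely source of the HPS8 shifts and a whole-chromosome change a less likely one. The bound was wrong for a line with such a trend, and this reading rests on a test chosen after the shifts were seen.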
